A study of Mus musculus with 6 samples.

How the data were processed

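RNA sequencing libraries were made from Trizol-extracted RNA of an immortalised mouse bone-marrow-derived macrophage line with a SMARTer mRNA-seq kit, per the labels' protocols. The 6 samples fall into 2 groups of 3 by the genotype in their titles, WT and A20KO. The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool, the use of strand and the annotation release are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart.

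The authors deposited 1 table of 21047 genes with a normalized signal per sample, per the file headers, which is not divided by gene length. In each library 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.001 reads, so the deposited signal is a read count divided by a size factor per library (0.9519 to 1.0491), and whole reads were recovered from it. Library totals were 13308840 to 15130697 reads, and no gene listed had 0 reads in all 6 libraries. The authors also deposited group means, a log2 fold change, and a p-value with its adjusted p-value per gene, and gene length in bases, per the file headers; the tool behind them is not given in the sources used here. In the authors' deposited table an adjusted p-value under 0.05 stands beside 5718 genes, 2901 higher and 2817 lower in A20KO. Of these genes 5709 passed here in the same direction and none passed in the opposite one.

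The unit turned out to be normalized reads, so the branch of the design fixed for normalized values was used. Values were transformed as log2(normalized read count + 1), genes with a mean of at least 1 were kept (17376), and genotype was tested with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; a second count required a change of at least 2-fold. A fold change on this scale understates the change of low genes. Count tests on the recovered reads were added as alternatives: edgeR 4.0.16 (quasi-likelihood) called 6686 of 12656 genes, 3315 higher and 3371 lower, and DESeq2 1.42.0 and limma-voom were also run. Figures were drawn with matplotlib 3.10.9, and tables made with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

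Before the data were examined, 36 gene lists were fixed from textbook knowledge, with the tests and the rule for named genes. Lists with at least 5 tested members (30) were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over those lists; camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way. Of the 30 lists, 8 passed camera with the preset correlation, 2 with an estimated one (NF-kB targets and the integrated stress and unfolded protein response), and 28 passed fry. Genes were named by rule: Tnfaip3, Nlrp3 and Nek7; the 10 largest rises and 10 largest falls among genes past the threshold whose genotypes did not overlap and whose higher group averaged at least 5 CPM, leaving out predicted genes, pseudogenes and unnamed transcripts; up to 4 members of each list by smallest adjusted p, 2 per direction where both occurred; and tested members of the inflammasome list. Where a group had no read, a fold was computed against a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio is given with an exact (Clopper-Pearson) 95% interval. Reads are not independent molecules, so intervals cover counting error only.

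The procedure was tested on simulated counts for the same comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed. Of 50 genes changed at each size, it called 38% at 1.25-fold, 68% at 1.5-fold, 72% at 2-fold and 96% at 4-fold among 17354 genes tested, with 4 calls among unchanged genes. The changed genes were drawn from those with a mean of at least 5. In the data 6917 of 17376 genes passed, far more than were changed here. The adjustment is then less strict, so these shares do not give the sensitivity of the real comparison. A simulated list of raised genes was called, and so was 1 of the other lists run on the simulation (33 in all), some of which held changed genes. Replicates were compared by a chi-square of their recovered reads: over genes with at least 10 reads in a pair it was 2.67 to 3.6 per degree of freedom, and 2.22 to 3.07 after leaving out genes that share at least 10% of their sequence with another gene, so replicates differed by more than sampling noise and each library was counted once.

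Of the gene identifiers 21038 occur in GENCODE M21, and 97.1% of these have the same start and end there, so its transcripts were used for GC content and for sequence shared between genes, measured as the share of a gene's 31-base words (1 in 8 sampled) also present in another gene. For the check on GC content and length, each library's deviations from the gene means were fitted with natural splines (5 degrees of freedom) of GC content, of length and of expression level over 17359 genes, and the fitted parts for GC content and length were removed, centred so that each library kept its mean. Of symbols on more than 1 line (7), the line with the highest mean was used in lists. Alternatives fixed before the data were examined were quantile normalization, no filter, a mean of at least 5, a pseudocount of 0.1, a replicate block, leaving out each library, limma without trend, a minimum fold, and the other list tests. Added after seeing the data were the count tests (edgeR with TMM, with RLE and without robust, DESeq2 and limma-voom), values rescaled with TMM factors, limma without robust, and leaving out chromosome 15 genes.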

Results

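RNA was sequenced from 6 samples of immortalised bone-marrow-derived macrophages (iBMDM), a mouse macrophage line. Of these libraries 3 were labelled wild type (WT) and 3 were labelled A20KO, a line made to lack A20, the ubiquitin-editing protein encoded by Tnfaip3 that restrains NF-kB signalling. The labels gave no treatment. The series asks about the role of A20 in macrophages, and the comparison was between the libraries of these lines as labelled. The WT libraries held 14802747, 15130697 and 13722924 reads assigned to genes, and the A20KO libraries held 14433653, 14388062 and 13308840. Values below are normalized read counts, given as mean ± SD with n = 3 per genotype unless stated, and log2 fold changes are A20KO over WT on the scale of log2(normalized read count + 1), with their standard error (SE). Nothing in the labels says that the 3 libraries of a genotype came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

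Tnfaip3 RNA was lower in the libraries labelled A20KO but remained present. Its normalized read counts were 389, 382 and 437 in the WT libraries and 194, 196 and 189 in the A20KO libraries, a log2 fold change of -1.06 (SE 0.101, limma adjusted p = 7.1e-14). Tnfaip3 (ENSMUSG00000019850) lies on the minus strand of chromosome 10 from 19000910 to 19015657 in mm10. The counts cover the whole gene and do not show which part of it was edited, so they check the labels only through the level of the RNA. The fall of Tnfaip3, itself an NF-kB target, did not stand apart from the falls of other NF-kB targets: 9 of the 24 tested NF-kB list members fell further. Both other genes of the series title were higher in A20KO. Nlrp3, the sensor of the NLRP3 inflammasome (ENSMUSG00000032691, chromosome 11 from 59541568 to 59566956, plus strand), had 853 ± 18.7 normalized reads in WT and 1041 ± 44.2 in A20KO, a log2 fold change of 0.29 (SE 0.0599, adjusted p = 5.6e-05). Nek7, the kinase that binds NLRP3 during its activation (ENSMUSG00000026393, chromosome 1 from 138482875 to 138620141, minus strand), had 920 ± 47.4 in WT and 1326 ± 17.1 in A20KO, a log2 fold change of 0.53 (SE 0.0568, adjusted p = 4.3e-12). For each of these 3 genes the A20KO values all lay on one side of the WT values.

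The lines differed across a large part of the transcriptome, with almost equal numbers of genes in each direction. Of 17376 genes tested with limma, 3519 were higher and 3398 were lower in A20KO at an adjusted p under 0.05, and 914 of the higher and 697 of the lower genes changed at least 2-fold. With testing limited to genes with a mean of at least 5, 6760 of 13815 passed. The counts of list members past the threshold, given below, are to be read beside these shares. In 8156 tested genes (46.9%) the values of the genotypes did not overlap, against 10% by chance. Among the genes open to naming, the largest fall was in Nos2. This gene, which encodes the inducible nitric oxide synthase, fell from 5296 ± 169 to 9.29 ± 4.69 normalized reads (log2 fold change -9.1, SE 0.349, adjusted p = 3.9e-05). Acod1, which makes itaconate, fell from 10935 ± 82.9 to 35.3 ± 12.4 (log2 fold change -8.3, SE 0.297, adjusted p = 3.5e-05). The other large falls were in Pzp, Ntng2, Il1f9, Cfap69, Lpar1 and Met, the hepatocyte growth factor receptor, which fell from 3230 ± 137 to 54.6 ± 14.5. P3h2 and Stfa3 had no read in the A20KO libraries and were at least 124.3-fold and at least 83.7-fold lower there, computed against a floor of 3 reads over the group. Among the largest rises were the complement subunits C1qb and C1qc, which had no read in the WT libraries and were at least 212.9-fold and at least 143-fold higher in A20KO. Rbp4, the plasma retinol carrier, was at least 114.9-fold higher on the same floor. Tmem273 (1 read in the WT libraries together, ratio 1092, 95% counting interval 208 to 45813), Tfpi (2 reads, ratio 600.3, 162 to 4857), Gpr176 (2 reads, ratio 568, 151 to 4511) and Agap2 (1 read, ratio 550.3, 104 to 23046) also rose. Clec10a, a lectin of alternatively activated macrophages, rose from 2.66 ± 1.52 to 403 ± 33.1, while Mvb12b and Frmd4b rose by 6.68 and 6.59 on the log2 scale. Intervals and floors cover counting error only.

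**Figure D1:**
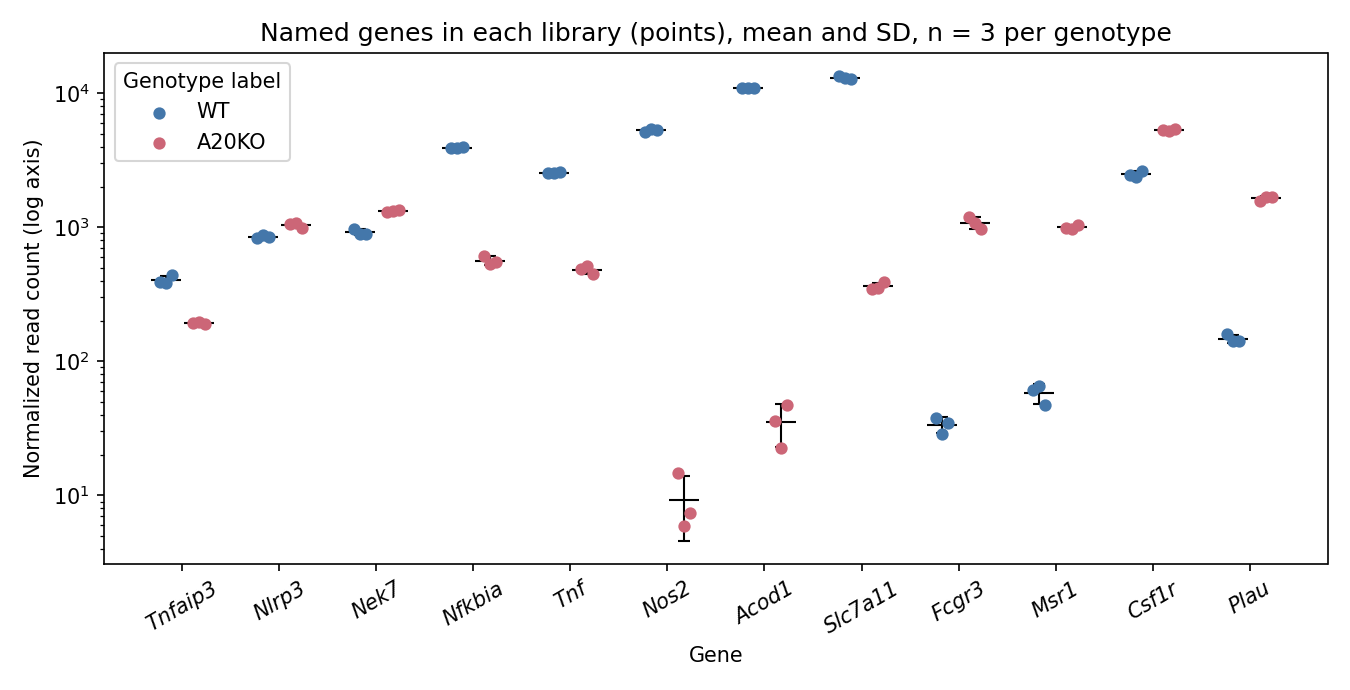
Normalized read counts (log axis) of 12 named genes in each library, as points, with the mean and SD of the 3 WT and the 3 A20KO libraries. Tnfaip3 lies between 382 and 437 in WT and between 189 and 196 in A20KO, and the genotypes do not overlap for any of the genes drawn.

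NF-kB feedback and target genes were lower in A20KO as a group. Of 24 tested members 20 fell, 2 rose and 2 did not pass, with a median log2 fold change of -0.92 (camera adjusted p = 1.6e-13; adjusted p = 0.041 with an estimated correlation). Adjusted over the list alone, 22 members passed. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, fell from 3920 ± 28.4 to 564 ± 43.2 normalized reads (log2 fold change -2.8, SE 0.0528, adjusted p = 8.3e-49). Tnfaip2 fell from 3847 ± 206 to 1091 ± 28.1. Ptgs2, the inducible cyclooxygenase, rose from 86.9 ± 6.98 to 319 ± 21.5. Cd83 rose from 4.86 ± 5.91 to 37.2 ± 10, a call that ended without WT replicate 3 (adjusted p = 0.12), with a pseudocount of 0.1 (adjusted p = 0.16) and without the variance trend (adjusted p = 0.066). The inflammatory cytokines went both ways, with 4 of 16 tested members higher and 4 lower (camera adjusted p = 0.56; 8 members passed adjusted over the list alone). Tnf fell from 2562 ± 25.6 to 483 ± 31.7 and Csf3 from 115 ± 21.9 to 1.35 ± 1.17, while Csf1, the macrophage growth factor, rose from 13.1 ± 2.66 to 315 ± 39.4. Of 12 tested chemokines 3 rose and 4 fell (camera adjusted p = 0.3; 7 passed adjusted over the list alone). Ccl3 fell by 1.45 and Ccl4 fell by 1.69 on the log2 scale, and Ccl9 rose by 0.49. Ccl24 also rose, with 0 reads in the WT libraries together and 14 in the A20KO libraries (limma adjusted p = 0.0081). That call ended without A20KO replicate 2 (adjusted p = 0.07). The chemokine test pointed down, as did the mean log2 fold change of -0.39, while the median was 0.12, also with the 2 members without a read in 1 genotype set at their bounds. Of 34 tested Toll-like and TNF receptor signalling components 9 rose and 13 fell (camera adjusted p = 0.16; 23 passed adjusted over the list alone). Irak3, an inhibitor of Toll-like receptor signalling, fell from 3352 ± 102 to 99.8 ± 14.6 and Tnfrsf1b, a TNF receptor, from 4564 ± 108 to 1031 ± 5.42. Tlr7 rose from 673 ± 76.9 to 1695 ± 34.6. Of 20 A20 partners and related ubiquitin enzymes 4 rose and 7 fell (camera adjusted p = 0.16; 11 passed adjusted over the list alone). Tnip1 and Tnip3, which bind A20, fell by 1.29 and 0.82 on the log2 scale.

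Inflammasome and pyroptosis genes changed in both directions, with 8 of 23 tested members higher, 9 lower and 6 not past the threshold. As a list they did not pass (camera adjusted p = 0.72, median log2 fold change 0.05), and 19 members passed adjusted over the list alone. Besides Nlrp3 and Nek7, the members that rose were Txnip (log2 fold change 1.02), P2rx7, the ATP-gated channel upstream of NLRP3 (0.87), Nlrp1b (1.94), Gsdmd, the pore-forming substrate of inflammatory caspases (0.38), Casp8 (0.3) and Casp1 (0.33, adjusted p = 4.6e-04, and 0.12 without the variance trend). Pycard, the adaptor ASC, fell from 580 ± 30.2 to 310 ± 49.2 normalized reads, a log2 fold change of -0.91 (SE 0.0902, adjusted p = 4.7e-13). Ninj1, Nlrc4 and Casp4 fell by 0.71, 0.66 and 0.71 on the log2 scale. Naip2, Naip6 and Naip5 also fell, but they share 32.1%, 36.4% and 50.5% of their sequence, as 31-base words, with other genes, so their counts are uncertain. Aim2 had a log2 fold change of -0.18 (adjusted p = 0.015), and its call ended without WT replicate 1 (adjusted p = 0.066), WT replicate 2 (0.062) or A20KO replicate 2 (0.065), and without the variance trend (0.094). Gbp2 had 16 reads in the WT libraries together and 2 in the A20KO libraries (adjusted p = 0.018), a call that ended without WT replicate 3 (0.13), A20KO replicate 1 (0.065) or A20KO replicate 3 (0.06), with DESeq2 (0.11) and without the variance trend (0.052). P2rx4 had 254.9 ± 12.8 normalized reads in WT and 303 ± 35.1 in A20KO (adjusted p = 0.057), and passed without WT replicate 3 (0.049) or A20KO replicate 2 (0.026), after quantile normalization (0.038), and on the recovered reads with edgeR (0.043, and 0.039 with RLE) and limma-voom (0.049). Il18 had 28.2 ± 4.34 and 43.8 ± 11.1 normalized reads (adjusted p = 0.071, and 0.049 with edgeR and RLE). Il1b was near the detection limit in both genotypes, with 8 reads in the WT libraries together and 11 in the A20KO libraries, and Il1a had 25 and 16. Neither passed (adjusted p = 0.56 and 0.6), and at this depth a small difference in either was not detectable. Gsdme and Brcc3 had log2 fold changes of 0.04 and 0.05 and did not pass (limma adjusted p = 0.83 and 0.61). Gsdmd lies on chromosome 15, where 355 of 662 tested genes were higher in A20KO and 47 were lower.

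Several lists of stress response, immediate early, glycolysis and hypoxia, and oxidative phosphorylation genes were lower in A20KO by camera with the preset correlation. None of 26 tested genes of the integrated stress and unfolded protein response rose and 24 fell, with a median log2 fold change of -0.71 (camera adjusted p = 1.3e-19; adjusted p = 0.041 with an estimated correlation; 24 passed adjusted over the list alone). Hspa5, the chaperone BiP, fell from 24150.3 ± 293 to 12997 ± 387 normalized reads, and Slc3a2, Mthfd2 and Sdf2l1 fell by 0.99, 0.98 and 1.2 on the log2 scale. Of 23 NRF2 and oxidative stress genes 16 fell and 2 rose, with a median of -0.5 (camera adjusted p = 6.3e-12; adjusted p = 0.11 with an estimated correlation; 18 passed adjusted over the list alone). Slc7a11, the cystine importer, fell from 13108 ± 288 to 364 ± 22.6, a log2 fold change of -5.17 (SE 0.0467, adjusted p = 2.5e-67), and the ferritin heavy chain gene Fth1 fell by 1.01 on the log2 scale, while Gclc rose by 0.29. Of 23 immediate early genes 14 fell and 4 rose, with a median of -0.66 (camera adjusted p = 9.0e-04; adjusted p = 0.31 with an estimated correlation; 19 passed adjusted over the list alone). Klf2 fell by 1.82 and Maff by 0.72, and Zfp36 and Egr3 rose by 0.49 and 1.7. Of 27 glycolysis and hypoxia response genes 15 fell and 4 rose, with a median of -0.2 (camera adjusted p = 0.0063; adjusted p = 0.31 with an estimated correlation and 0.051 without the variance trend; 19 passed adjusted over the list alone). Slc2a1, the glucose transporter, fell by 0.82 on the log2 scale, and the members with the smallest adjusted p among those that rose, Pfkm and Ndrg1, both lie on chromosome 15. Of 33 nuclear-encoded oxidative phosphorylation genes 17 fell and 2 rose, with a median of -0.13 (camera adjusted p = 0.0063; adjusted p = 0.44 with an estimated correlation and 0.051 after quantile normalization; 19 passed adjusted over the list alone). Uqcrq and Cox4i1 fell by 0.38 and 0.23. The 2 that rose were Ndufs3 (0.17, limma adjusted p = 0.026) and Cox6c (0.14, adjusted p = 0.04). Their calls ended under 4 and 8 alternatives, among them limma without the variance trend (adjusted p = 0.14 and 0.26). These list tests assume a small preset correlation between genes. Regrouping the 6 libraries gave up to 6 lists past the same threshold, against 8 for the genotypes. Each regrouping mixed the genotypes unequally between its groups, so part of the genotype difference stayed in it. Its list count is therefore not a level reached by chance alone.

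Macrophage identity genes were higher in A20KO as a list but moved in both directions. Of 29 tested members 16 rose and 9 fell, with a median log2 fold change of 1.19, the same with the 4 members without a WT read set at their bounds (camera adjusted p = 0.0032; adjusted p = 0.14 with an estimated correlation; 25 passed adjusted over the list alone). Fcgr3, an Fc receptor for IgG, rose from 33.7 ± 4.7 to 1081 ± 111 normalized reads (log2 fold change 4.97, SE 0.124, adjusted p = 3.0e-42), and Msr1, a scavenger receptor, rose from 58.0 ± 9.67 to 999.6 ± 39.4. Lgals3 and Lyz2 fell by 0.56 and 0.57 on the log2 scale. Of 17 alternative activation and scavenger receptor genes 8 rose and 5 fell (camera adjusted p = 0.72; 13 passed adjusted over the list alone); besides Clec10a, Clec7a, the beta-glucan receptor, rose from 2.98 ± 1.95 to 116 ± 1.95, and Clec4d and Clec4e fell by 1.04 and 0.77 on the log2 scale. Of 22 growth factor and cytokine receptors 9 rose and 10 fell (camera adjusted p = 0.64; 20 passed adjusted over the list alone). Csf1r, the receptor for Csf1, rose from 2497 ± 129 to 5348 ± 76.1, Il6st rose by 1.17, and Il1r1 and Il4ra fell by 1.72 and 0.79. MHC class I antigen presentation genes rose in 9 and fell in 4 of 17 (camera adjusted p = 0.12; 13 passed adjusted over the list alone), among them Nlrc5, the transactivator of class I genes, which rose by 2.99. MHC class II antigen presentation genes rose in 5 and fell in 2 of 9 (camera adjusted p = 0.15; 7 passed adjusted over the list alone), with Ctss higher by 0.63 and Cd80 lower, as it fell by 0.6. Of 25 extracellular matrix, protease and adhesion genes 10 rose and 7 fell (camera adjusted p = 0.057; 18 passed adjusted over the list alone). That list passed without any filter on low values (adjusted p = 0.049), without WT replicate 1, 2 or 3 (0.05, 0.048 and 0.05) and, as an alternative chosen after seeing the data, without chromosome 15 genes (0.0098). Plau, the urokinase plasminogen activator, rose from 148 ± 10.9 to 1651 ± 76.4. Of 32 lysosome and autophagy genes 7 rose and 10 fell (camera adjusted p = 0.23; 17 passed adjusted over the list alone), with Atp6v0d2 higher by 3.54 and Ctsk, which fell by 0.89, lower.

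**Figure D2:**
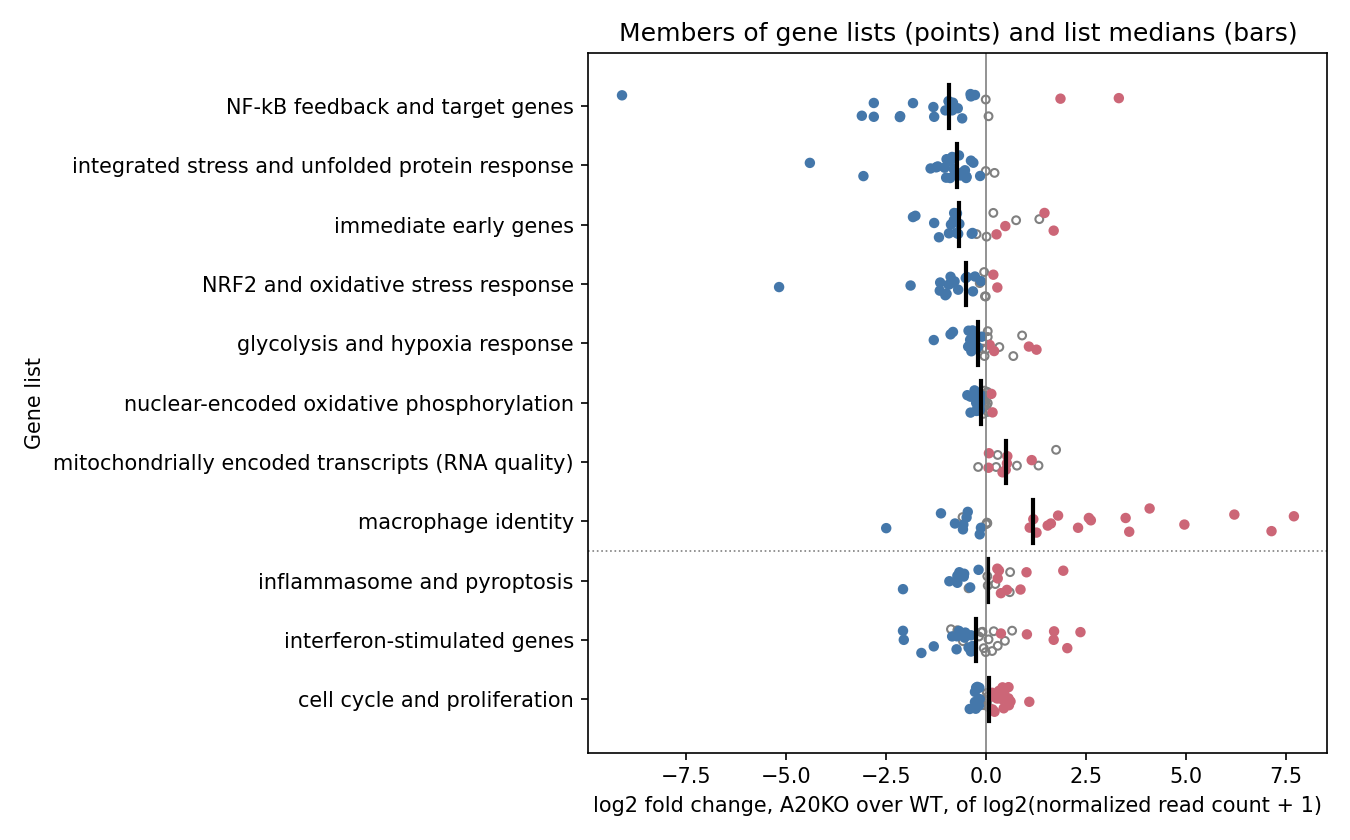
Log2 fold change, A20KO over WT, of each tested member (points) of the 8 lists that passed camera with a preset correlation (above the dotted line) and of 3 that did not (below it). Filled points passed the gene test, red higher and blue lower in A20KO, open points did not, and bars are list medians, from -0.92 for NF-kB targets to 1.19 for macrophage identity.

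Cell cycle genes changed in both directions. Of 35 cell cycle and proliferation genes 17 rose and 12 fell (camera adjusted p = 0.074; 29 passed adjusted over the list alone), and the list passed after quantile normalization (adjusted p = 0.042) and without a filter (0.049) and, added after seeing the data, without chromosome 15 genes (0.045). Ccnd1, a cyclin of the first gap phase, rose from 2108 ± 76.3 to 4500.2 ± 129 normalized reads and the replication licensing gene Mcm6 rose by 0.57 on the log2 scale, while the mitotic genes Bub1 and Top2a fell by 0.4 and 0.24. Of 21 p53 target genes 6 rose and 9 fell (camera adjusted p = 0.27; 15 passed adjusted over the list alone), with Cdkn1a higher by 0.85 and Mdm2 lower, as it fell by 0.8. Of 24 apoptosis and necroptosis genes 5 rose and 12 fell (camera adjusted p = 0.074; 18 passed adjusted over the list alone). The death receptor gene Fas fell from 251 ± 39.7 to 18.8 ± 7.4, Cflar, an inhibitor of caspase-8 and an NF-kB target, fell by 0.82, and Bcl2 rose by 2.36. Interferon-stimulated genes rose in 6 and fell in 14 of 34 (camera adjusted p = 0.23; 20 passed adjusted over the list alone), with Oasl1 lower, as it fell by 1.3, and Trim30a higher by 1.03. Of 23 cholesterol biosynthesis genes 6 rose and 12 fell (camera adjusted p = 0.15; 19 passed adjusted over the list alone), among them Fdft1, which fell by 0.73, and Cyp51, which rose by 0.52. Of 15 lipid efflux and LXR target genes 6 rose and 8 fell (camera adjusted p = 0.56; 14 passed adjusted over the list alone); Apoe rose from 343 ± 46.3 to 1693 ± 34.2, and Abcg1 fell by 0.6.

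Markers of other cell types were mostly low, and those that differed went both ways. The lists of fibroblast, mast cell and basophil, lymphocyte, erythroid and megakaryocyte, and epithelial and endothelial markers and of sex-chromosome transcripts each had fewer than 5 tested members. Among these, Acta2 had 66.5 ± 3.11 normalized reads in WT and 17.7 ± 4.38 in A20KO, Tpsab1 35.3 ± 3.71 and 1.68 ± 0.612, Cd79b 151 ± 24.4 and 67.5 ± 7.21, and Pf4, a platelet chemokine that myeloid cells also express, 5.32 ± 2.14 and 161 ± 18.6; each passed the gene test. Pecam1 and Cdh5 had at most 9 reads in a genotype and did not pass, and Xist had 5 reads in the WT libraries and 0 in the A20KO libraries. Of 8 neutrophil and granulocyte precursor markers 1 rose and 2 fell (camera adjusted p = 0.41; 5 passed adjusted over the list alone), with Lcn2 falling from 1855 ± 49.8 to 110.3 ± 4.18. Of 6 dendritic cell markers 3 rose (camera adjusted p = 0.25; 3 passed adjusted over the list alone), including Zbtb46, from 34.8 ± 4.86 to 75.2 ± 5.16. Of 9 osteoclast markers 5 rose and 2 fell (camera adjusted p = 0.21; 7 passed adjusted over the list alone), with Ocstamp higher by 1.86 on the log2 scale and Acp5 at least 10.9-fold lower. Ctsk, also on the osteoclast list, was not low: it had 17071 ± 496 normalized reads in WT and 9228 ± 69 in A20KO. Among the lists that report on RNA quality, mitochondrially encoded transcripts were higher in A20KO, where 7 of 13 rose and none fell (camera adjusted p = 5.2e-05; adjusted p = 0.31 with an estimated correlation; 8 passed adjusted over the list alone). All genes of the mitochondrial chromosome together held 2.0% to 2.2% of reads in the WT libraries and 2.6% to 2.8% in the A20KO libraries. The log2 fold changes of the list members that rose ran from 0.07 for mt-Co1 to 1.15 for mt-Cytb. Several mitochondrial genes share sequence with nuclear copies, 68.2% of it for mt-Nd4, so their counts are uncertain. Of 15 replication-dependent histone genes 2 rose, Hist1h1c and Hist1h2bc (camera adjusted p = 0.4; 2 passed adjusted over the list alone). Of 8 nuclear-retained RNAs 5 rose and 1, Neat1, fell (camera adjusted p = 0.21; 7 passed adjusted over the list alone). Counts are also less certain for Clec10a, Ntng2, Trim30a, Fcgr3, Lyz2, Pfkm, Fdft1, Ndufs3, Hist1h1c and Hist1h2bc. These genes share between 10.2% and 32.0% of their sequence with other genes.

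Genes of chromosome 15 were higher in A20KO as a group, a feature singled out after its values were seen. Of 662 tested chromosome 15 genes 355 were higher and 47 lower. Among its 267 genes with a mean of at least 500 normalized reads the median log2 fold change was 0.42, with quartiles at 0.2 and 0.61, against medians from -0.09 to 0.08 on the other autosomes and the X chromosome. The median was 0.41, 0.44 and 0.41 in the 3 A20KO libraries, each taken against the mean of the WT libraries. Tested as gene sets, 1 of 20 chromosomes passed (chromosome 15, camera adjusted p = 9.1e-14; adjusted p = 0.0067 with an estimated correlation). Without the chromosome 15 genes 3148 genes were higher and 3338 lower.

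**Figure D3:**
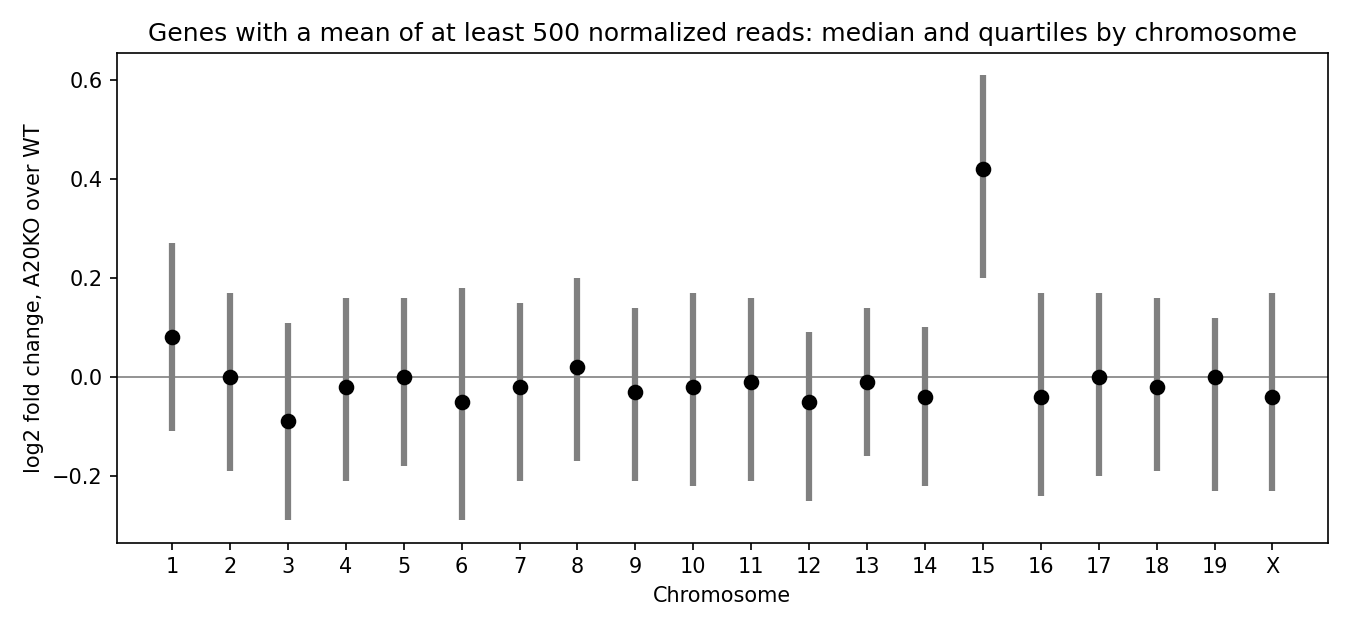
Median (points) and quartiles (lines) of the log2 fold change, A20KO over WT, of genes with a mean of at least 500 normalized reads, by chromosome. Chromosome 15 has a median of 0.42, and the other chromosomes have medians from -0.09 to 0.08.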

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

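The count tests, the TMM rescaling, limma without robust and the fit without chromosome 15 genes were chosen after seeing the data. Against 6917 genes that differed, other settings without a minimum fold called from 4775 (limma without trend, 4529 of them among the 6917) to 6920 (TMM rescaling, 6893 among them), and leaving out 1 library gave 6214 to 6515. Requiring a 2-fold change left 1611 genes, by its own construction. Leaving out 1 library moved that count to between 1461 and 1519. Over all settings it ran from 1180 (edgeR quasi-likelihood, among 12656 genes tested) to 1690 (no filter on low values). With edgeR 619 of these genes were higher and 561 lower, against 914 and 697 in the main fit. Genes higher in A20KO numbered 3108 to 3338 and genes lower 3000 to 3177 without 1 library. Of the 8 lists called, 2 passed with an estimated correlation and 28 of 30 passed fry, which does not compare a list with other genes; leaving out 1 library gave 8 or 9 lists. Tnfaip3, Nlrp3 and Nek7 kept their direction and their side of the threshold under every alternative run, with log2 fold changes of -1.09 to -1.0, 0.27 to 0.32 and 0.5 to 0.57 without 1 library. No named gene or list reversed while called. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.004, -0.011 and 0.002. With the replicate number as a block 6729 genes and 8 lists passed, with 3432 genes higher and 3297 lower, and 1601 past 2-fold. Of 168 tested genes chosen by rule or named later, 10 lost their call and 3 gained one under at least 1 alternative; among lists 6 lost it and 20 gained it, all 20 by fry and some also by another setting. Depth limits the low genes: with 0 reads in a genotype the data give only a bound on the fold. The cause of the lower count without the trend was not tested.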

Other observations

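The tests of exchanged labels, of GC content and length, of windows and of the share of genes above 0 on chromosome 15, of sequence shared by uneven genes and of the number of genes over splits of the samples were chosen after the result, or values close to it, had been seen. Within the cell cycle list, the 6 members that encode the replication licensing complex rose together: log2 fold changes were 0.35 for Mcm2, 0.57 for Mcm3, 0.58 for Mcm4, 0.45 for Mcm5, 0.57 for Mcm6 and 0.4 for Mcm7, whose count is less certain because it shares 28.5% of its sequence with other genes. Each of these genes passed in the same direction under every alternative run, and they were singled out after their values were seen.

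NF-kB targets were lower in the libraries labelled A20KO, although A20 restrains NF-kB. A trend with GC content or gene length was argued against, since correcting each library for both left the median of the list at -0.93 (from -0.92) and its camera adjusted p at 5.4e-13. An exchange of the genotype labels cannot be told apart from the labels as given: Tnfaip3 RNA is lower where the label says A20KO, but it is an NF-kB target too, and 37.5% of the list fell further, so its level may follow NF-kB activity in place of the edit. Whole-gene counts do not show the edited part. A difference between the lines other than A20, such as one that arose while a clone was grown, stays open. The labels name 1 line per genotype, and the design does not separate such a difference from the loss of A20. Nor do the labels say that WT and A20KO libraries shared a day or culture. A difference of that kind is not separated from the genotype either.

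The rise across chromosome 15 is a candidate for a difference in the number of copies of that chromosome between the lines. A few genes with large changes were argued against, as 88.4% of its 267 genes with at least 500 normalized reads lay above 0, against 38.0% to 63.3% on other chromosomes. A GC or length trend was argued against too: after correction the chromosome 15 median was 0.36. A first version of this correction, which was not centred and moved all genes alike, gave 0.2, but its excess over the other autosomes was 0.42 in both versions and 0.43 uncorrected. More copies could account for the pattern, since the excess was at least 0.33 in each of 3 bins of expression level, and all 10 windows of 25 genes along the chromosome had medians between 0.27 and 0.5, against -0.28 to 0.2 for 213 windows elsewhere. The windows and the highest bin use only genes among these 267, and the middle bin, with means of 189.4 to 830.8, holds some of them. Only the lowest bin, with means up to 189.2, holds none of them, and its excess was 0.33. Bins and windows show how the shift was spread, but do not separate more copies from another difference along the whole chromosome. A ratio of 4 copies to 3 would give 0.42 and 3 to 2 would give 0.58, but RNA does not measure copies, and DNA was not analysed here.

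Among genes with a mean of at least 500 normalized reads, 11 differed at least 2-fold between libraries of 1 genotype. Gapdh, often used as a reference gene, had 707, 798 and 3985 normalized reads in WT and 5166, 2201 and 836 in A20KO, and Sumo2, Rps27a and mt-Atp6 were uneven as well. For mt-Atp6 the values were 322 ± 132 in WT and 1113 ± 483 in A20KO (limma adjusted p = 0.059). As 98.5% of the sequence of mt-Atp6 is shared with other genes, its count is uncertain under every setting. It passed without A20KO replicate 3 (0.044), at a mean of at least 5 (0.049) and without robust (2.8e-06). It also passed with a replicate block (6.0e-25), although the replicate numbers did not pair the samples. On recovered reads it passed with edgeR (0.045, with RLE 0.044, without robust 1.5e-07) and DESeq2 (0.0013). Reads shared with near-identical copies, which a counting tool may assign unevenly, could account for some of the uneven genes. Of these, 72.7% (8 of 11) share at least 10% of their sequence with another gene, against 12.3% of 5860 other genes at this level. The share was 80.8% to 100% for Gm10123, Rps27rt, mt-Atp6, Gm28437 and Gm6563. It was only 28.5% for Gapdh, 25.3% for Rps27a and 19.0% for Sumo2, whose largest within-genotype folds were 6.18, 2.42 and 3.98. Whether shared reads can move Gapdh, Rps27a and Sumo2 that far was not tested. The 3 genes below 10% are Acod1, Nos2 and Cd28, which have few reads in one genotype. No biological explanation was tested. These genes were chosen after their values were seen.

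The 6 samples can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The split by genotype gave 6917 genes, and the highest of the other 9 gave 0. Each of the other splits puts both genotypes in each group, so the genotype difference adds to the spread within groups. Their 0 genes therefore say little about whether the genotypes differ. For lists the split by genotype gave 8, and the highest other gave 6. Part of the genotype difference stays between the groups of the other splits, so their list counts are not a chance level. In each case 1 of the 10 splits gave a result as large, the real one.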
